A study of Mus musculus with 3 samples.

How the data were processed

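TBX5 is a T-box transcription factor of the developing heart and forelimb. Its genomic binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) of hearts from CD-1 mouse embryos, an outbred stock, at embryonic day 14.5. The series holds 3 samples, namely 2 biological replicates precipitated with an anti-TBX5 antibody and 1 input sample of chromatin that was not precipitated. Libraries held fragments selected between 200 and 650 bp and were read as single ends of 50 bases, per the labels' protocols.

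Bowtie2, SAMtools, MACS2 and ChIPseeker were used with the mm10 build, per the submitters' processing notes, in which no versions or settings are given. The peaks come from 1 call on the pooled TBX5 samples, per the file headers and names, so no value per replicate exists in the files used here. The fold enrichment of each peak is the authors' ratio of pooled ChIP fragments over the local background at the summit, the position of highest signal. The −log10 p and −log10 q of each peak, like the score, are the authors' values from the same call, and the deposited score is 10 times −log10 q truncated to a whole number. All are properties of a peak in this list, and they were used only to describe, rank and filter peaks within it. A deposited table adds, per peak, the signed distance of the summit to a transcription start, a promoter class, the overlap with regions of 6 histone marks taken from ENCODE, a chromatin class made from these and the overlap with TBX3 regions. The tissue and stage of the histone mark and TBX3 regions and the overlap rules are not given in the sources used here. H3K4me1, H3K4me3 and H3K27ac have a pair of region files each, and a peak counted as marked if either file marked it.

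The read depth per sample is not given in the sources used here. The summit pileup, which is the number of pooled ChIP fragments over the summit, and the background were instead solved from the fold, (pileup + 1)/(background + 1), and from −log10 p as an upper Poisson tail. A whole-number pileup matched −log10 p within 0.0005 for all 12436 peaks (largest misfit 0.000242). On 985 simulated peaks the pileup was recovered exactly in 100% of cases. Intervals given beside a fold are the exact 95% Poisson interval of the pileup with the background held fixed. They cover counting error of the pooled fragments only, not the spread between hearts or replicates. Intervals of shares are exact Clopper-Pearson 95% intervals, and they treat peaks as independent, which clustered peaks are not.

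The RefSeq gene table used here belongs to GRCm38.p6, the assembly that mm10 names, and gives the body of each gene without strand, transcripts or exons. Positions are 1-based on mm10. The 21631 protein-coding genes on chromosomes 1 to 19 and X were used, and a gene was called bound if at least 1 summit lay in its body or within 10 kb of it. A summit near several genes was counted for each of them. All entries of the 27 gene lists matched a symbol (0 unmatched). For each list the share of bound genes was set against 10000 random lists matched on 10 groups of extended gene length, with a two-sided permutation p and Benjamini-Hochberg adjustment over the 27 lists. In simulations on the same genes, 4.00% of 500 lists of 30 long genes without any planted effect had p below 0.05. Without length matching it was 12.4%. Of such lists bound 2 times as often, 78.2% were found at an unadjusted p below 0.05, with genes hit independently. That share does not carry over to shorter lists or to p adjusted over the 27 lists. Among bound genes, overlap with TBX3 or H3K27me3 regions was set against random bound genes with a similar number of summits.

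Medians of groups of peaks were compared by a two-sided permutation test with 100000 resamples, and ratios of medians have bootstrap intervals from 1000 draws. In simulations, 6.00% of equal groups had p below 0.05 and 99.0% of groups that differed by 20% were found. Shares were compared by Fisher's exact test, two-sided, which also treats peaks as independent. A common odds ratio over strata of 5 fold groups by 5 width groups was computed beside it. Locations and clustering were tested against 1000 shuffles of the summits within the span of annotated genes of their own chromosome. Assembly gaps, which the plan left out, and other sequence where no peak can be called stayed in these spans. Counts per chromosome were tested against 1000 shuffles over these spans of all chromosomes together. Simulated uniform summits gave an observed to shuffled ratio of 1.00 for clustering, with p below 0.05 in 3.00% of runs, and planted pairs were found in 100% of runs. The smallest p that these designs can give is 1e-05 for permutations, 0.001 for shuffles and 0.0001 for random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

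Tests, gene lists and the rule for named genes were fixed before the data were examined, except where said otherwise. The rule takes 21 fixed heart genes, the 10 peaks of highest fold by nearest gene and the 5 genes with the most summits. From each list past the threshold it takes the 4 members with the strongest peak and up to 3 unbound members in alphabetical order, and from other lists at most 2 members with the strongest peak. Some genes that the rule picks are not used here. The tests of the chromatin classes and of overlap with TBX3 and histone mark regions, by peak and by gene list, were chosen once the table was seen to hold these columns. Alternatives were peaks with −log10 q of at least 10, the stronger peaks by fold, other distances, shuffles and matching. Promoter strength was compared with the authors' class, within 2000 bp of a start, with 1 kb and 3 kb as alternatives. Gene bodies and gene ends replaced the planned classes of location, since exons, introns, untranslated regions and starts are not used here. The planned search for T-box and partner motifs needs genome sequence and was not run.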

Results

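TBX5 binding was mapped in mouse hearts at E14.5 in 2 pooled ChIP samples against 1 input sample. The deposited list held 12436 peaks, which covered 3.51 Mb of mm10. The same peaks, with the same start and end, stood in all 3 deposited lists. The median width was 251 bp and the median fold enrichment over background 5.67 (range 2.11 to 85.6). The median summit pileup was 22 fragments, a count that carries a 95% Poisson interval of 13.8 to 33.3, and the median background was 2.83. These medians were taken separately and need not belong to the same peak. Fold enrichment reached at least 20 in 506 peaks (4.07%), and 5156 peaks (41.5%) had −log10 q of at least 10. Since the peaks were called on pooled samples, the spread between the replicates could not be computed for any value.

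Known and presumed TBX5 target genes were examined first. Of 21 heart and cardiopulmonary genes fixed in advance, 12 had a summit in the gene body or within 10 kb. Gja5, which encodes the gap junction protein connexin 40 of atria and conduction system, had 3 summits. The strongest lay beyond the gene at 97062788 to 97063363 on chromosome 3, with 56.9-fold enrichment (50.2 to 64.4) from 253 fragments. Scn10a, a sodium channel gene, held 2 summits in its body, the stronger at 119632071 to 119632647 on chromosome 9 with 22.2-fold enrichment (17.3 to 28.0), and both overlapped TBX3 regions. Ryr2, the sarcoplasmic calcium release channel, had 4 summits and a strongest fold of 19.1 (14.99 to 24.0) at 12104273 to 12104654 on chromosome 13, in the gene body.

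Peaks at promoters marked several genes of the contractile and natriuretic programme. Tnnt2, cardiac troponin T, had a 16.7-fold peak (13.5 to 20.5) 87 bp upstream of a start at 135835961 to 135836419 on chromosome 1. Nppa, which encodes atrial natriuretic peptide, had 1 summit 229 bp upstream of a start, with 9.93-fold enrichment (7.44 to 13.0), at 147999777 to 148000854 on chromosome 4. Nppb, the adjacent gene of the same family, had no summit within 10 kb, and the nearest lay 13288 bp away. Myh6, the alpha myosin heavy chain, had 5 summits, 4 of them in the authors' promoter class, and none above 5.52-fold (3.61 to 8.10). The promoter-class peak at 54939529 to 54939709 on chromosome 14 lay outside the gene body, at the opposite end from the other promoter-class summits. Hcn4, the pacemaker channel, had 3 summits with a highest fold of 9.67 (6.85 to 13.3). Among transcription factors, Gata4 had 4 summits (highest 6.01-fold, 3.87 to 8.97) and Nkx2-5 had 2 (highest 5.26-fold, 3.53 to 7.56). Tbx3 had 1, a 5.28-fold peak (3.93 to 6.94) 6 bp from its start. A stronger peak of 21.9-fold (18.6 to 25.5) lay 19064 bp upstream of the same start, outside the 10 kb window.

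TBX5 also bound its own gene. Tbx5 had 8 summits, the strongest with 19.1-fold enrichment (14.99 to 24.0) at 119796409 to 119796818 on chromosome 5. That peak lay 38081 bp upstream of the start that the authors' annotation assigned to it, with its summit just inside the edge of the RefSeq gene body. Of the 8 summits, 3 overlapped H3K27me3, a mark of Polycomb repression, and 2 overlapped TBX3 regions. Fixed genes without a summit in the window included Nppb, Atp2a2, Kcnj2, Hand2, Wnt2, Gli1, Osr1 and Foxf1. The nearest summit lay 15961 bp from Foxf1, 19036 bp from Atp2a2, 32659 bp from Gli1 and 38449 bp from Hand2. It was over 100000 bp away for Wnt2 (108551 bp), Kcnj2 (138398 bp) and Osr1 (336743 bp). A missing summit means that none passed the authors' threshold in the pooled samples, and binding below it was not detectable at this depth.

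**Figure D1:**
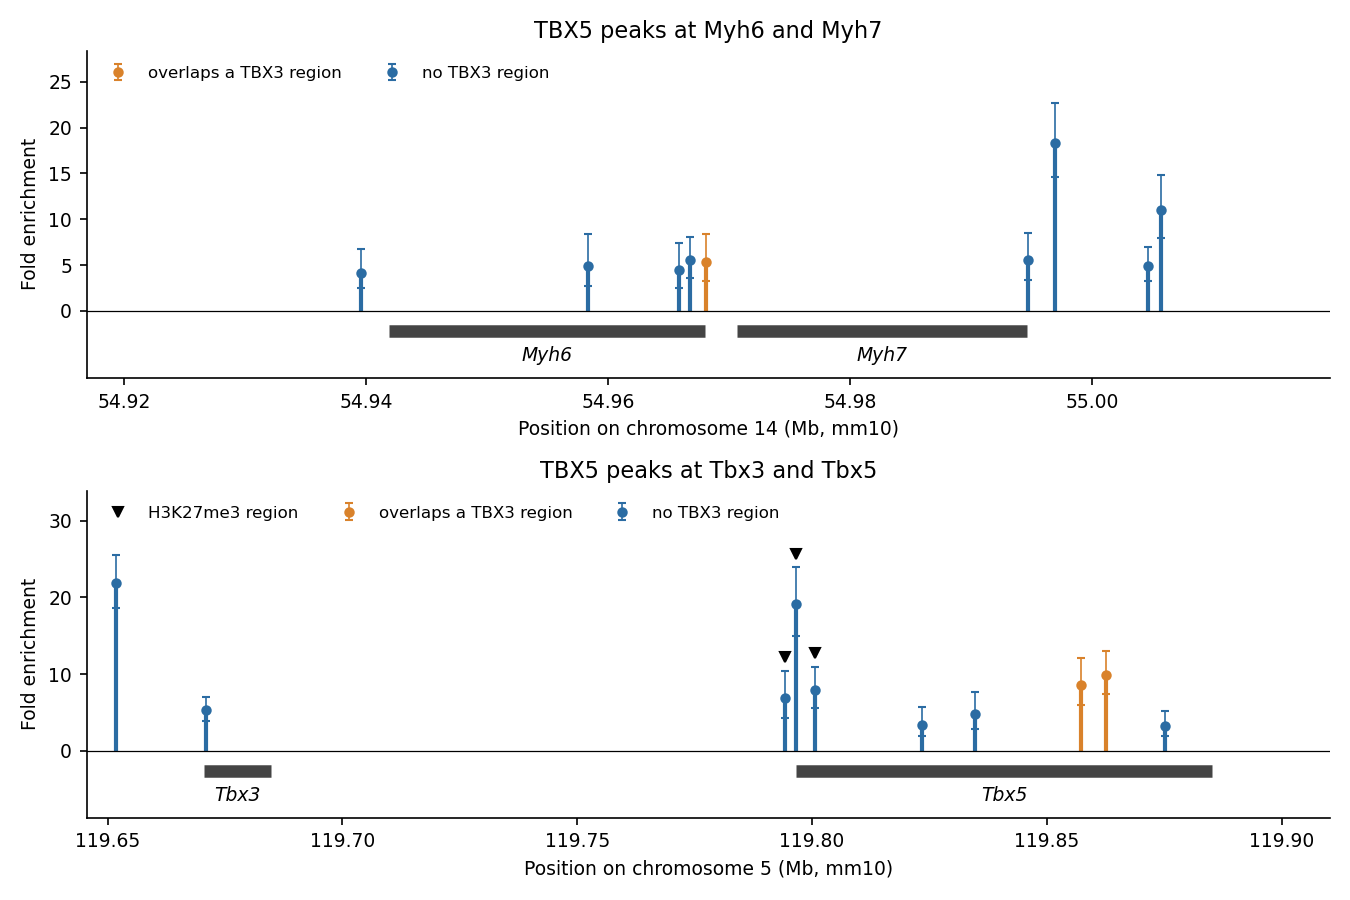
TBX5 peaks at Myh6 and Myh7 on chromosome 14 and at Tbx3 and Tbx5 on chromosome 5, as fold enrichment (vertical axis) by position in Mb on mm10 (horizontal axis), with bars for the 95% Poisson interval and grey blocks for gene bodies. The strongest peak near Myh7 reaches 18.3-fold, and the 3 peaks at the left end of Tbx5 overlap H3K27me3 regions (triangles).

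The strongest peaks of the list lay away from gene starts. All 10 peaks of highest fold were active non-promoter peaks in the authors' classes, between 62.2-fold and 85.6-fold, and 1 of them overlapped a TBX3 region. The highest lay at 38169672 to 38170243 on chromosome 15, 49295 bp from the body of Odf1, with 85.6-fold enrichment (75.7 to 96.5). The next lay at 21173669 to 21174085 on chromosome 10, 12912 bp from Myb, with 74.7-fold (64.8 to 85.7). Peaks near Slc4a3, Ipo8, Eef2kmt, Mn1 and Slc35b3 lay from 40768 to 524069 bp outside these genes, whereas those of Tns1, Hltf and Myl2 lay inside the gene body. The Myl2 peak, at a ventricular myosin light chain gene, had 62.2-fold enrichment (55.2 to 69.8) at 122094407 to 122094958 on chromosome 5. Although inside the RefSeq body, it lay 6296 bp upstream of the start that the authors' annotation assigned to it. The nearest gene is a name by position and need not be the regulated gene. The genes with the most summits were Nav2 with 21, Cdkal1 and Esrrg with 19 each, Gse1 with 17 and, tied at 16, Cacna1c, Rbm20 and Maml3. These are long genes, which hold more summits by chance.

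Gene groups were compared to find which were bound more often than genes of similar length. The random lists were matched on gene length only, not on expression or open chromatin in the heart. An excess in a list of heart genes therefore need not be particular to TBX5. Of the 21631 protein-coding genes 6475 (29.9%) had a summit, and 318 had at least 5. Against random lists matched on gene length, 10 of 27 lists were bound more often and 1 less often. Lists share members, such as Gja5 and Kcnh2 in the conduction and atrial fibrillation lists and Myl2 in the sarcomere and ventricular lists. The 10 calls are therefore not independent of each other. Genes of the sarcomere, the contractile unit of muscle, stood highest by share, with 30 of 32 bound (93.8%, against 34.4% in matched lists, a ratio of 2.72). Myl2, Tcap (24.5-fold, 19.7 to 30.1), Myh7 (18.3-fold, 14.6 to 22.7) and Tnnt2 had the strongest peaks there, and Myl3 and Xirp2 had none. The Tcap peak lay outside the gene body, and its assigned start, 5992 bp from the summit, lay outside that body too. It need not belong to Tcap. Of genes for conduction and ion channels, 23 of 30 were bound (76.7% against 39.1%). Members with strong peaks were Gja5, Kcnh2 (33.8-fold, 29.3 to 38.8) and Gjd3 (32.4-fold, 26.98 to 38.6). Cntn2, Kcna5 and Kcnj2 had no summit. With promoter peaks alone the conduction call was lost (adjusted permutation p = 0.750). The Gjd3 peak also fell within 10 kb of Top2a, so it was counted for both genes. Among calcium handling genes 17 of 20 were bound (85.0% against 48.0%). Cacna1c, the L-type calcium channel, had a 42.6-fold promoter peak (36.7 to 49.2) and Jph2, a junctional protein of the sarcoplasmic reticulum, a 29.7-fold peak (24.6 to 35.6). Ryr2 and Cacna2d1 (16.9-fold, 12.3 to 22.8) followed, and Atp2a2, Fkbp1b and Sln had none.

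Cardiac transcription factor genes were bound in 25 of 34 cases (73.5% against 35.3%). Meis2 (38.3-fold, 31.5 to 46.3), Myocd (21.5-fold, 16.8 to 27.2), Prdm16 (20.02-fold, 16.6 to 23.9) and Tbx5 had the strongest peaks, and Hand2, Irx3 and Irx4 had none. Genes at human atrial fibrillation loci were bound in 35 of 41 cases (85.4% against 44.3%), with Gja5, Kcnh2, Kcnj5 (26.7-fold, 22.2 to 31.9) and Scn10a strongest and Cav2, Esr2 and Hand2 unbound. For each of these lists except calcium handling the adjusted p was 0.00054, from a permutation p of 0.0001, the smallest that these random lists can give. For calcium handling it was 0.00154. Atrial and ventricular genes were both bound more often, 11 of 15 (73.3% against 32.2%, adjusted permutation p = 0.0021) and 9 of 11 (81.8% against 29.0%, adjusted p = 0.00135). Bmp10 (33.8-fold, 27.8 to 40.7), Kcnj3 (16.0-fold, 11.9 to 21.1) and Dkk3 (13.7-fold, 10.1 to 18.3) led the atrial list with Tbx5, while Clu, Nppb and Nr2f2 had no summit. Smpx (11.4-fold, 7.96 to 15.9) and Lbh (10.4-fold, 7.30 to 14.4) followed Myl2 and Myh7 in the ventricular list, while Cited1 and Irx4 had no summit. Both calls missed the threshold when the gene body was not extended, at an adjusted permutation p of 0.0513 each, and the atrial call also at 50 kb (adjusted permutation p = 0.0521). Without extension the ratios were 2.03 for atrial and 2.73 for ventricular genes, against 2.28 and 2.83 in the main test. At 50 kb the atrial ratio was 1.60. The ventricular call was also lost with promoter peaks alone (adjusted permutation p = 0.0812).

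Of genes for septation and congenital heart disease 23 of 38 were bound (60.5% against 35.9%, adjusted permutation p = 0.00486). Rbm20, a splicing regulator, held 16 summits with a strongest fold of 24.2 (19.2 to 30.03), and Chd7 reached 17.6-fold (14.1 to 21.8). Myh11 reached 18.3-fold (14.9 to 22.4), and Cfc1, Creld1 and Eln had no summit. The signalling pathways BMP and TGF-beta had 22 of 33 genes bound (66.7% against 39.5%, adjusted permutation p = 0.0021), among them Bmp10, Bmp7 (27.1-fold, 23.2 to 31.5), Bmpr1b (21.4-fold, 17.1 to 26.6) and Smad3 (19.8-fold, 16.6 to 23.5), but not Bmp2, Bmp5 or Grem1. Fatty acid oxidation and mitochondrial genes had 17 of 30 bound (56.7% against 31.7%, adjusted permutation p = 0.00687). There the regulators Esrrg (23.0-fold, 17.7 to 29.5), Ppara (12.6-fold, 9.55 to 16.3) and Ppargc1a (10.9-fold, 7.60 to 15.2) stood ahead of the enzyme gene Cpt1a (8.44-fold, 5.48 to 12.5). Acadvl, Cd36 and Cox6a2 had no summit. With only the peaks of −log10 q of at least 10, neither the BMP nor the fatty acid call remained (adjusted permutation p = 0.0643 and 0.333). Both were also lost without extension of the gene body (adjusted permutation p = 0.0513 and 0.436) and with the stronger peaks by fold (0.187 and 0.253). The BMP ratios under these settings, in the order given, were 1.74, 1.60 and 1.58, against 1.69 in the main test. The fatty acid ratios were 1.58, 1.44 and 1.67, against 1.79. With non-promoter peaks alone the fatty acid call was lost as well (adjusted permutation p = 0.0982, ratio 1.78).

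Lists of other cell types of the heart did not pass the threshold with all peaks within 10 kb. Bound genes numbered 5 of 19 for endocardium and valves (26.3% against 34.9%), 6 of 20 for endothelium (6.94 expected) and 6 of 22 for epicardium and fibroblasts (27.3% against 31.7%). They numbered 6 of 13 for smooth muscle (46.2% against 35.5%) and 5 of 20 for blood (25.0% against 25.0%). Other settings gave 2 calls, with smooth muscle genes bound more often for peaks of −log10 q of at least 10 (ratio 2.66, adjusted permutation p = 0.0248) and endocardial and valve genes by the nearest gene of each summit (12 of 19, ratio 1.87, adjusted permutation p = 0.0103). Single members still had strong peaks, such as Pecam1 with 27.3-fold (22.4 to 33.0) and Fli1 with 14.2-fold (10.3 to 19.3) among endothelial genes. Tbx18 (13.8-fold, 10.0 to 18.5) and Tek (6.84-fold, 4.69 to 9.67) were the strongest members of the epicardial and endocardial lists. For Wnt (13 of 30, 43.3% against 37.9%), hedgehog (7 of 18, 38.9% against 36.4%) and Notch signalling (10 of 19, 52.6% against 30.9%) the adjusted p values were 0.654, 1.00 and 0.0767. Notch genes passed under 3 other settings, namely 50 kb, the nearest gene and circular shifts (adjusted permutation p = 0.0174, 0.0103 and 0.0396). Fgf10, in the limb and the lung lists, had a 9.30-fold poised peak (6.29 to 13.3). Of these lists 4 of 28 limb genes (14.3% against 25.9%) and 7 of 19 lung and foregut genes (36.8% against 26.2%) were bound, with adjusted p values of 0.300 and 0.446. The lung and foregut list passed by the nearest gene (adjusted permutation p = 0.00891).

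Among lists for unrelated tissues and housekeeping functions 1 passed the threshold, on the lower side. Olfactory and vomeronasal receptor genes were bound in 7 of 1463 cases (0.478% against 10.1%, adjusted permutation p = 0.00054), and Olfr606, Olfr607 and Olfr608 shared 1 of those peaks. The random lists drew genes independently and were not matched on mappability, that is, how well reads can be placed. The low share therefore need not reflect TBX5 binding. Epidermal keratin genes had 1 of 22 bound (4.55% against 23.6%, adjusted permutation p = 0.0752), a 3.09-fold peak at Tgm3. Hepatocyte genes had 4 of 24 bound (16.7% against 25.0%), neuronal genes 6 of 26 (23.1% against 36.9%) and skeletal muscle genes 8 of 22 (36.4% against 28.5%), with adjusted p values of 0.604, 0.236 and 0.604. Ribosomal protein genes (28 of 97, 28.9% against 20.4%) and cell cycle genes (15 of 35, 42.9% against 27.04%) had an adjusted p of 0.0733 each. Both lay above the matched level, and both passed with circular shifts (adjusted permutation p = 0.0112 and 0.0145), ribosomal genes also at 50 kb (0.00405) and cell cycle genes with promoter peaks alone (0.0154). Keratin genes passed on the lower side without length matching (0.0232) and with circular shifts (0.0347). The ribosomal list holds 10 genes of ribosomal S6 kinases through its name rule, and the kinase-like Rps6kc1 had its strongest peak (22.8-fold, 17.98 to 28.6). For the lists of other heart cell types the adjusted p was at least 0.604. Genes, not hearts, are the units of these tests, so the p values describe this peak list.

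**Figure D2:**
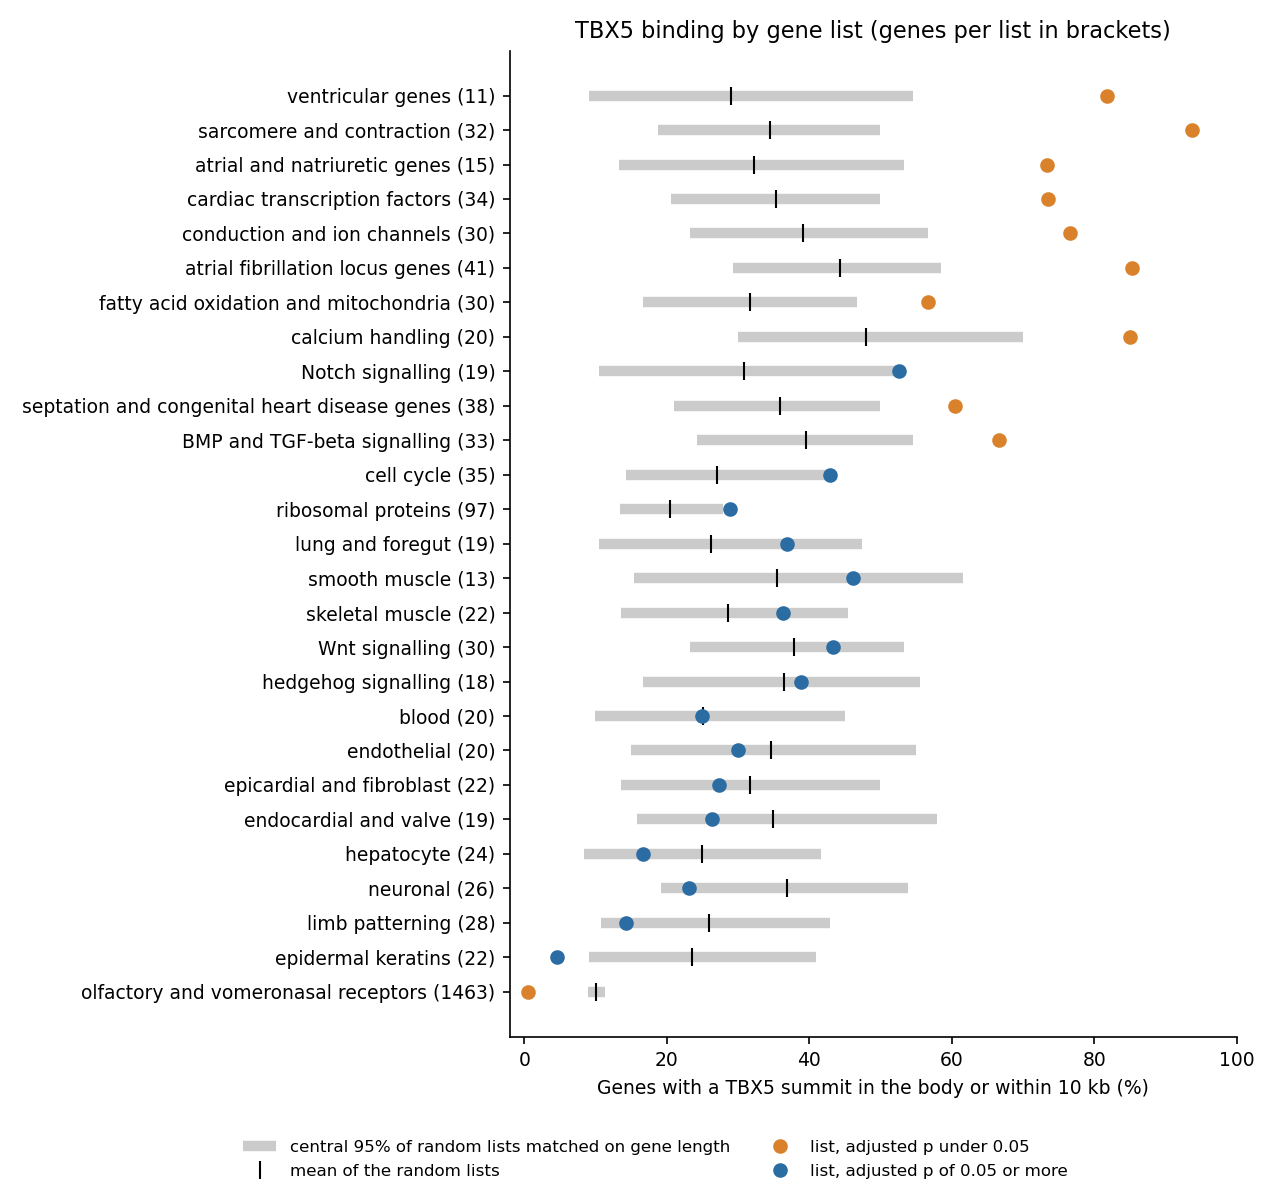
Share of genes with a TBX5 summit in the gene body or within 10 kb (horizontal axis, percent) for 27 gene lists, with dots for the lists, grey bars for the central 95% of 10000 random lists matched on gene length and black ticks for their mean. The sarcomere list reached 93.8% and the receptor list 0.478%, and both lay outside their grey bars.

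Peaks were then placed relative to genes. Summits lay within 2000 bp of a transcription start, the authors' promoter class, in 3055 peaks (24.6%, 23.8 to 25.3), while 32.0% lay at 10 to 50 kb and 15.5% beyond 100 kb. Of the 9381 non-promoter peaks 41.1% lay upstream of the nearest start. Summits fell inside protein-coding gene bodies in 58.8% of cases against 40.5% for shuffled summits, a ratio of 1.45, and within 2000 bp of either gene end in 22.7% against 5.87%, a ratio of 3.87 that fell to 2.26 with −log10 q of at least 10 (13.2% against 5.84%). Peaks also clustered, since 32.9% of summits had another within 10 kb against 9.61% after shuffling (ratio 3.42, and 1.66 for 50 kb), and 29.2% against 7.34% among non-promoter peaks. Shuffles within 1 Mb of each summit gave smaller ratios, of 1.201 for gene bodies (48.9% expected), 2.93 for gene ends (7.76% expected) and 2.35 for clustering (13.98% expected). Each of these had a shuffle p of 0.001, the smallest that the shuffles can give. Assembly gaps were not left out of the shuffles, which can raise these ratios. The promoter share depended on strength, as promoters made up 52.6% of the weakest and 7.36% of the strongest of 5 equal groups of peaks by fold.

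Promoter peaks had a lower fold than the others, with a median of 4.40 against 6.23, a ratio of 0.706 (0.696 to 0.721). The permutation p was 1e-05, the smallest that the permutations can give. The pileup at called promoter summits was slightly higher, with a median of 23 against 21 fragments (ratio 1.10, 1.05 to 1.10), and the background was 1.71 times as high (4.24 against 2.47). Cacna1c, Kcnh2 and Tnnt2 were exceptions to the low fold of promoters, at 42.6-fold, 33.8-fold and 16.7-fold.

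The chromatin state of the bound regions was compared next. H3K27ac, an acetylation of active regulatory regions, covered 73.5% of all peaks (72.8 to 74.3), 93.9% of promoter peaks and 66.9% of the others. H3K4me1, typical of enhancers, covered 82.9% of non-promoter and 39.7% of promoter peaks. H3K4me3, typical of promoters, covered 12.6% and 90.9%. The repressive marks lay at few peaks, with H3K27me3 at 203 (1.63%, 1.42 to 1.87) and H3K9me3 at 30 (0.241%, 0.163 to 0.344). No expected share was computed for any mark. H3K4me1, H3K4me3 and H3K27ac counted either of a pair of region files and the other marks a single file, which limits comparison between marks. None of the 6 marks lay at 10.1% of peaks. The authors' classes follow these marks without exception in 12436 of 12436 peaks. Active non-promoter peaks, with H3K27ac and no H3K27me3, numbered 6237 (50.2%). Active promoters numbered 2905 (23.4%) and poised non-promoter peaks, with H3K4me1 but no H3K27ac, 1763 (14.2%). A further 1255 non-promoter peaks (10.1%) fell in the class of other peaks, and 72 promoter peaks did too. Repressed classes held 87 non-promoter and 54 promoter peaks, and bivalent classes 39 and 24. In that rule a bivalent promoter needs a repressive mark and every file of H3K4me3, H3K27ac and H3K9ac. Repressed promoters can therefore still carry active marks in some files. Poised peaks had a median fold of 6.41 against 6.15 at active non-promoter peaks, a ratio of 1.04 (1.01 to 1.07, adjusted p = 0.0165, permutation test). The call ended with −log10 q of at least 10 (ratio 1.00, permutation p = 0.732). The order reversed for the summit pileup, at 20 against 22 fragments.

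Overlap with regions of TBX3, a related T-box factor of the conduction system, was the last comparison. TBX3 regions overlapped 3362 TBX5 peaks (27.03%, 26.3 to 27.8). The share was 45.0% at promoters and 21.2% elsewhere, an odds ratio of 3.04 (2.78 to 3.32, adjusted p = 1.87e-136, Fisher's exact test). Among non-promoter peaks it was 28.0% with H3K27ac and 7.34% without, an odds ratio of 4.92 (4.25 to 5.71, adjusted p = 9.77e-135, Fisher's exact test). H3K9ac, H3K4me1 and H3K4me3 at non-promoter peaks went with odds ratios of 3.78 (3.41 to 4.20), 4.41 (3.60 to 5.45) and 2.46 (2.16 to 2.81). For H3K27me3, over all peaks, the shares were 25.1% with and 27.1% without the mark, with an odds ratio of 0.904 (0.643 to 1.25) and an adjusted p of 0.578 (Fisher's exact test). All these tests treat peaks as independent, which clustered peaks are not. Their p values may be too small and their intervals too narrow. By class, the share ran from 3.19% in other and 10.0% in poised non-promoter peaks to 46.2% in active promoters. It fell from 38.2% in the weakest to 20.9% in the strongest of the 5 groups by fold. Scn10a, Cacna1c, Jph2, Tcap and Pecam1 had a strongest peak that overlapped TBX3, whereas Gja5, Myl2, Meis2 and Bmp10 did not. None of 24 gene lists differed from other bound genes in TBX3 overlap after adjustment. At an unadjusted permutation p below 0.05, 2 did, namely conduction and ion channels (7 of 23 bound genes against 11.6 expected, adjusted p = 0.530) and fatty acid oxidation (13 of 17 against 8.23, adjusted p = 0.322).

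**Figure D3:**
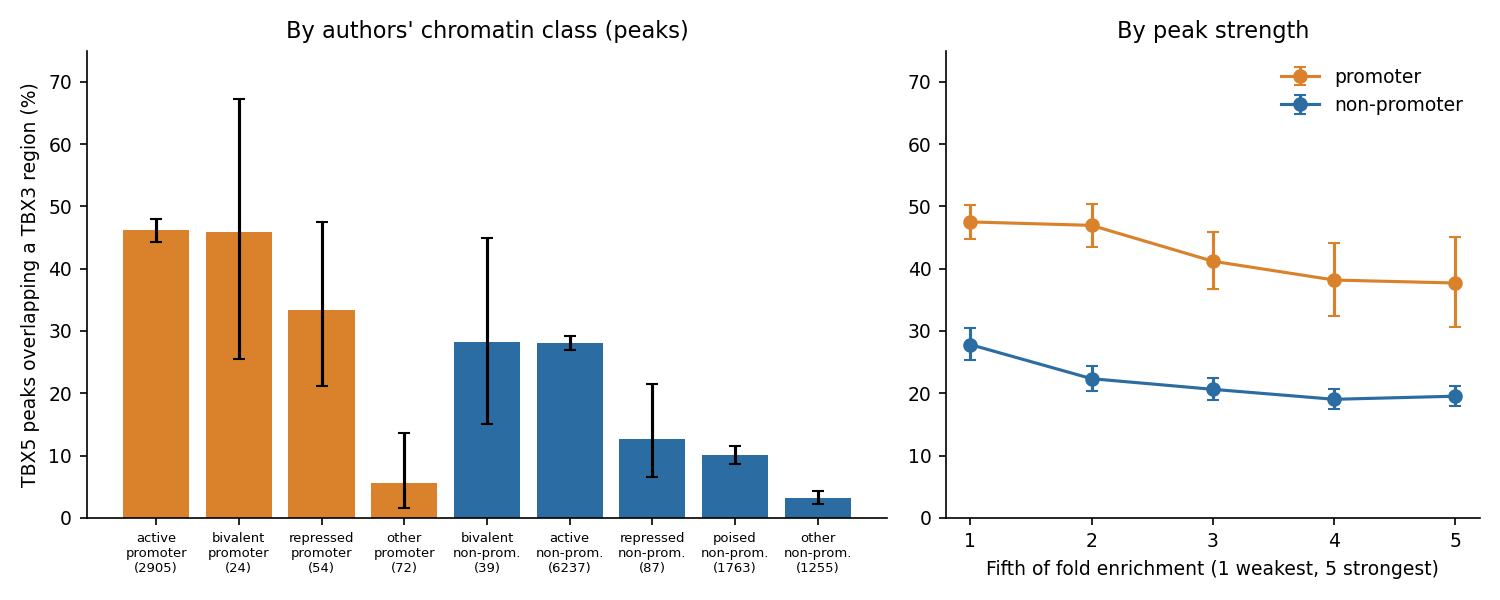
Share of TBX5 peaks that overlap a TBX3 region (vertical axes, percent) by the authors' chromatin class, with the number of peaks in brackets, and by 5 groups of fold enrichment, with exact 95% intervals as bars. Promoter peaks lie above non-promoter peaks in each group, from 47.5% to 37.7% against 27.8% to 19.5% between the weakest and the strongest.

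Peaks were unevenly spread over chromosomes. Chromosome X held 152 peaks, or 0.891 per Mb against 5.06 per Mb on the autosomes, and 0.186 times the number expected from its length. Smpx and Syp, with promoter-class peaks of 11.4-fold (7.96 to 15.9) and 15.7-fold (12.0 to 20.2), were among the X-linked genes bound. The Syp peak lay outside the gene body but within 10 kb of it. Its assigned start, 100 bp from the summit, lay outside that body too, so the peak need not be at a Syp promoter. Chromosomes 11, 19 and 18 exceeded the number expected from length by ratios of 1.34, 1.30 and 1.26, and chromosome 14 was the lowest autosome at 0.867. For these 5 chromosomes the adjusted p was 0.004, from the smallest p that the shuffles can give. In all 12 chromosomes passed the threshold, and with −log10 q of at least 10 only X, 11, 18 and 19 did, so 8 calls were lost, that for chromosome 14 among them (ratio 0.916, adjusted p of 0.413). Scaled by genes, X stayed lowest at 15.7 peaks per 100 protein-coding genes, against 57.5 over all chromosomes, and chromosome 18 highest at 103. Chromosomes 11 (48.4) and 19 (51.2) then lay below the overall level and chromosome 14 (60.8) above it. Shuffles place summits independently, so clustering makes these p values too small.

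**Figure D4:**
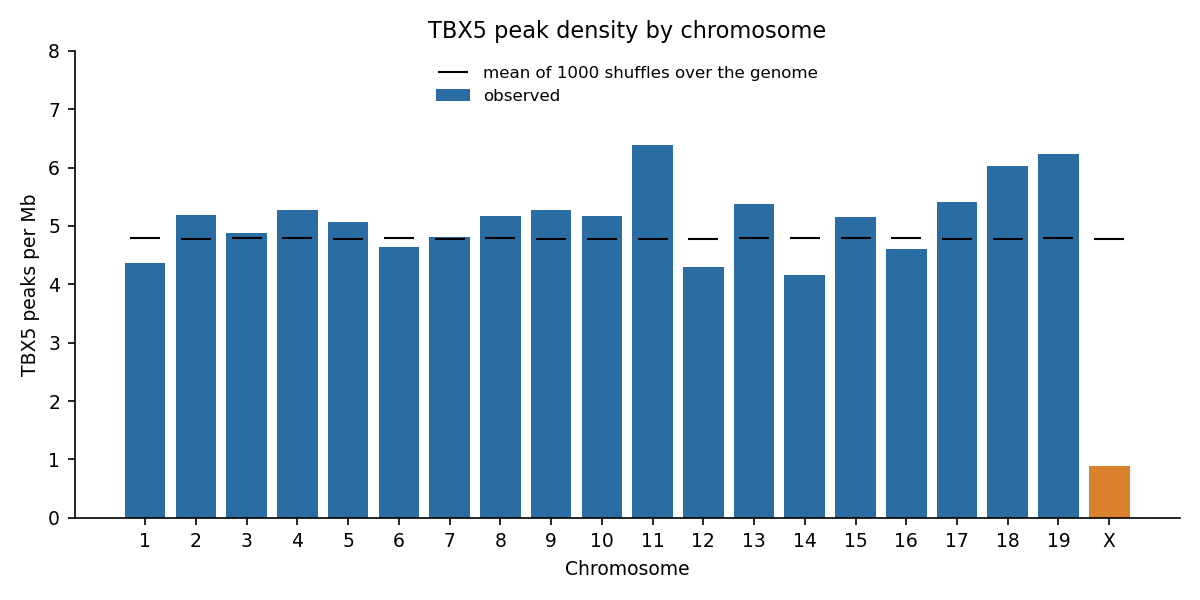
TBX5 peaks per Mb (vertical axis) on each chromosome (horizontal axis), with black lines for the mean of 1000 shuffles over the genome. Chromosome X stands at 0.891 per Mb and chromosome 11 at 6.39 per Mb.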

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

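Of 51 alternatives of the main comparisons 40 kept the result, which for a count means within 1.5 times the main count, for a share within its 95% interval and for a test the same direction and side of the threshold. Tests of chromatin classes, TBX3 overlap, list overlap with marks, single kinds of peaks, circular shifts and local shuffles of gene location were added after seeing the data. With −log10 q of at least 10 the list held 5156 peaks, the promoter share was 14.1%, the ratio for chromosome 14 was 0.916 (adjusted shuffle p of 0.413), the ratio of poised to active fold was 1.00 (permutation p = 0.732) and 0 lists differed in H3K27me3 overlap (3 at an unadjusted p below 0.05). Fewer peaks entered there. The promoter share was 21.1% within 1 kb and 26.9% within 3 kb, which follows from the distance. The poised to active ratio was 0.909 for pileup. Lists bound more often, 10 in the main count, numbered 6 without extension of the gene body and up to 13, with the nearest gene and with circular shifts. Lists bound less often numbered 2 without length matching and 2 with circular shifts, where keratin genes were added. For endocardial and valve genes the nearest-gene count reversed the direction and passed the threshold (ratio 1.87, adjusted permutation p = 0.0103). The cause was not tested for these. Over 243 alternatives of single lists 219 kept their call, 12 lost it and 11 gained it, the latter for Notch, ribosomal, cell cycle, keratin, smooth muscle and lung genes. The calls for 6 of 11 lists held throughout, namely sarcomere, calcium handling, cardiac transcription factors, septation and congenital heart disease, atrial fibrillation loci and the receptor genes. Not run were the motif searches (no genome sequence used here), the count of summits within 1 kb of starts (no strand used here) and leaving out a replicate (pooled peaks). No paired analysis was possible because the groups share fewer than 2 replicate numbers and the peaks were pooled.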

Other observations

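The tests of H3K27me3 and TBX3 overlap by gene list were chosen after the deposited table was seen. The check of the pileup needed for a call was added after the pileup ratio was seen. The other tests of the explanations weighed here were written down beforehand, though the TBX3 comparison itself was chosen after the table was seen. TBX5 peaks with H3K27me3 included several at developmental regulators. Of 25 bound cardiac transcription factor genes 5 had such a summit, against 0.921 expected from other bound genes with as many summits (ratio 5.43, adjusted permutation p = 0.0336 over 24 lists). They were Hand1 (6.17-fold, 4.08 to 8.99), Irx1 (6.45-fold, 4.33 to 9.29), Irx2 (3.49-fold, 2.14 to 5.40), Nkx2-5 (3.53-fold, 2.22 to 5.36) and Tbx5, and all 5 were of the bivalent class, which also carries active marks. All 3 summits at the atrial growth factor gene Bmp10 had H3K27me3, the strongest with 33.8-fold enrichment (27.8 to 40.7). Skeletal muscle, ventricular and BMP and TGF-beta genes had ratios of 9.88, 7.04 and 3.89 at an unadjusted p below 0.05, but missed the adjusted threshold (adjusted permutation p = 0.196, 0.222 and 0.236). With only the peaks of −log10 q of at least 10 the ratio for cardiac transcription factors was 5.73, from 3 of 16 bound genes against 0.523 expected, and the call ended with fewer genes (adjusted permutation p = 0.194). The strongest H3K27me3 peaks of the list lay in Kif16b (57.0-fold, 48.3 to 66.7) at 142641736 to 142642159 on chromosome 2, in Bcas3 (49.0-fold, 42.8 to 55.9) and in Tenm4 (44.4-fold, 38.0 to 51.6).

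The lower fold of promoter peaks was set against 1 technical explanation, a higher background at promoters. The ratio of median pileups, promoter over other peaks, was 1.10 (1.05 to 1.10). Only called peaks enter this ratio, and at the median background a promoter peak needs a pileup of 14 to pass the weakest p of the list, against 10 elsewhere. This selection favours a ratio above 1. Among called peaks the lower fold went with a higher median background (4.24 against 2.47) and not with a lower median pileup. Whether the background alone lowers the fold at promoters beyond the called peaks is not decided by the ratio and stays open. No biological explanation was tested.

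The scarcity of peaks on the X chromosome was set against a pair of explanations. A single X copy would halve the fragments at most. After halving the pileup and background of autosomal peaks, 75.8% still passed the weakest p of the list. That was far above the X density of 17.6% of the autosomal density (14.9 to 20.6). The halved background could fall below 1.48, the lowest background of any peak in the list, so 75.8% may be too high. Under this setting, lower copy number is unlikely to be the whole cause. Gene number and length do not account for it either, since 9.94% of 966 X-linked genes had a summit against 29.9% of matched autosomal genes (27.2 to 32.5). Mappability of the X and the kinds of genes it holds stay open, as does a biological difference in X-linked binding, which the design cannot test.

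The higher TBX3 overlap of promoter peaks could reflect their strength or width. Within strata of fold and width the odds ratio was 2.31 (2.10 to 2.55) against 3.04 without strata. Fold and width, as grouped here, thus did not account for all of the difference. Differences within the strata remain, and the pileup was not among the strata. The origin of the TBX3 regions is not given in the sources used here, and a bias of that assay toward open promoters stays open, as does shared T-box binding as a hypothesis.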
